A study of Arabidopsis thaliana with 36 samples.

How the data were processed

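Total RNA of whole rosettes was extracted with a Trizol method, treated with DNase and sequenced on the BGISEQ-500 platform at BGI Genomics, per the labels' protocols. The 36 libraries cover the lines Col0, mbf1c and jub1 at NonA, ACC, Deacc2 and Deacc4, with 3 libraries per group, per the labels. The deposited values are raw counts per gene, 1 table per library, with an unstranded column and a column for each strand, and no normalisation. Reads were aligned to TAIR10 with STAR 2.6.0c, per the submitters' processing notes, which also name DESeq2 without giving its role. The annotation release behind the counts is not given in the sources used here.

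Each table held 34262 genes and 4 lines for reads outside single genes. Gene counts per library ran from 14407060 to 63178347, 87.2% to 93.0% of reads. Reads in no gene made up 0.286% to 0.837%, ambiguous reads 3.13% to 5.86%, multimapping reads 2.54% to 5.20% and unmapped reads 0.399% to 1.31%. Organellar genes took 0.0179% to 0.153% of gene counts and the 10 most abundant genes 5.50% to 17.8%. The first strand column held 50.4% to 52.0% of the stranded counts, so by the rule written before the data were examined the unstranded column was used. No 2 libraries of a group were copies of each other: the smallest chi-square per degree of freedom between libraries of a group was 17.7. Gene names came from the reference annotation TAIR10.1, which named 32548 of the genes; it was also used for neighbours, exonic length and GC content, and none of its coordinates are printed. PCR copies were not removed with molecular identifiers, so depth limits refer to counting error only.

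Genes were kept by edgeR's filterByExpr by group, which left 20679, and scaled with TMM. 1 quasi-likelihood model with a term per group was fitted to all 36 libraries (common dispersion 0.1056), and 31 contrasts were tested with Benjamini-Hochberg adjustment within each contrast at 0.05: 15 of temperature within a line, 8 of a mutant against Col0 at a condition, 2 averaged over conditions and 6 interactions. Unless another tool is named, adjusted p-values of genes come from edgeR. Fold changes are log2 with standard errors, and levels are CPM after TMM scaling, with SD. CPM used no prior count, and list means per library used a prior count of 2.

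In all, 18 gene lists were fixed before the data were examined: cold regulon, sugar and proline, flavonoid and anthocyanin, hypoxia, heat shock, gibberellin and brassinosteroid, photosynthesis, cell wall growth, cell cycle, ribosome biogenesis, circadian clock, jasmonate, salicylate defence, abscisic acid, oxidative and mitochondrial stress, senescence, floral organ markers and root markers. Of their genes 277 were measured. Lists were tested with limma's camera on log2 CPM at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. Members were counted over all genes and adjusted over the list alone.

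Named genes followed a rule written before the data were examined. It gave MBF1C and JUB1 in every group and up to 4 members per list with the smallest adjusted p. It also gave the 10 largest rises and 10 largest falls for Col0 at ACC against NonA and at Deacc2 against ACC, and the 5 and 5 largest for other contrasts, among called genes with a mean of at least 5 CPM and no overlap between libraries of the compared groups. Near-identical copies (over 95% identity over at least 200 bases, by BLAST) and exons shared with other genes were looked up for 317 genes: 8 had a copy, 70 shared exonic bases with a gene on the opposite strand and 5 with one on the same strand. Counting without strand cannot tell the reads of opposite genes apart, and the tables hold ambiguous reads outside the gene counts.

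Alternatives were RLE scaling, DESeq2, no filter, a replicate block, only the compared groups, no organellar genes, the first strand column, each replicate number left out of all groups, each library left out singly (for counts), and an estimated correlation for lists. A correction for transcript length (a loess trend of each library taken out as an offset), the same with the replicate block, and a block within each condition were added after the data were seen. The trend was fitted to deviations from the gene mean over all 36 libraries. It therefore also takes out differences between conditions or lines that follow length, and a call that it ended may be a real response. Overlaps of calls between contrasts were set beside the value for independent lists and beside 20 simulations of unchanged groups.

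Groups share replicate numbers in the labels. Whether the numbers pair the libraries was checked before calls were compared, from the correlation across genes of deviations from the group mean. Every same-number pair was over 0.1 in 8 of 23 contrasts: mbf1c at ACC against NonA and at Deacc2 against ACC, jub1 at Deacc4 against NonA, mbf1c against Col0 at NonA, ACC, Deacc2 and Deacc4, and jub1 against Col0 at Deacc2. The median correlation was 0.204 for libraries of the same number (−0.611 to 0.751) and −0.079 for other numbers. The sample titles write the number after "Exp", in every group. Beyond this the labels do not say what libraries of one number had in common.

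The tests were tried on simulated counts for 20679 genes, 200 of them changed, before use on the real counts. For Col0 at ACC against NonA edgeR recovered 8% of genes changed by a log2 of 1 and 72% of those changed by 2, with 2 false calls, and DESeq2 24% and 80%, with 23 false calls. For mbf1c against Col0 at NonA edgeR recovered 15% and 71% (3 false calls) and averaged over conditions 73% and 99% (8 false calls). For the interaction of mbf1c with ACC against NonA it recovered 1% and 33% (0 false calls). A planted list of 20 genes was called each time and 0 of 17 other lists were. The simulated genes were drawn independently of one another. These counts of false calls therefore do not carry over to real libraries, where genes vary together.

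Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, matplotlib 3.10.9 and BLAST 2.17.0. Co-expression networks, freezing tolerance and the denser time course that the labels mention were not analysed here. Groups of 3 were not screened for outlying libraries, since 3 values are too few for that test.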

Results

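RNA from whole rosettes of Arabidopsis thaliana was sequenced in 36 libraries on the BGISEQ-500 platform. The wild type Col0 was compared with the mutant lines mbf1c and jub1, whose names refer to MBF1C (AT3G24500), a stress-related transcriptional coactivator, and JUB1 (AT2G43000, JUNGBRUNNEN1), a NAC transcription factor. Plants entered the experiment at 28 days and were harvested before cold (NonA), after 3 days at 4 °C (ACC), and after 2 days (Deacc2) or 4 days (Deacc4) back under warm long days. Counted from that age, they were 3, 5 and 7 days older at ACC, Deacc2 and Deacc4 than at NonA. Each of the 12 line and condition groups had 3 libraries, which the labels describe as biological replicates, so the p-values measure the spread between these samples. Libraries held 14407060 to 63178347 counts in genes, 87.2% to 93.0% of all reads, and 21324 to 23256 genes were detected in each. The first principal component, with 50.1% of the variance, separated the ACC libraries from the rest, and the second held 20.4%.

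Libraries also differed in how expression followed transcript length. The slope of log2 CPM per doubling of exonic length ran from −0.761 to 0.471 over the 36 libraries. Its mean was −0.334 ± 0.289 (SD, n = 9) at NonA, 0.269 ± 0.157 at ACC, 0.073 ± 0.266 at Deacc2 and −0.008 ± 0.288 at Deacc4. Across genes, which are not independent replicates, the Col0 response to cold had a Spearman rho of 0.447 with exonic length. Counts of changed genes that a correction for this trend moved by over 1.5 times are given with the comparison concerned or in the section on processing.

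**Figure D1:**
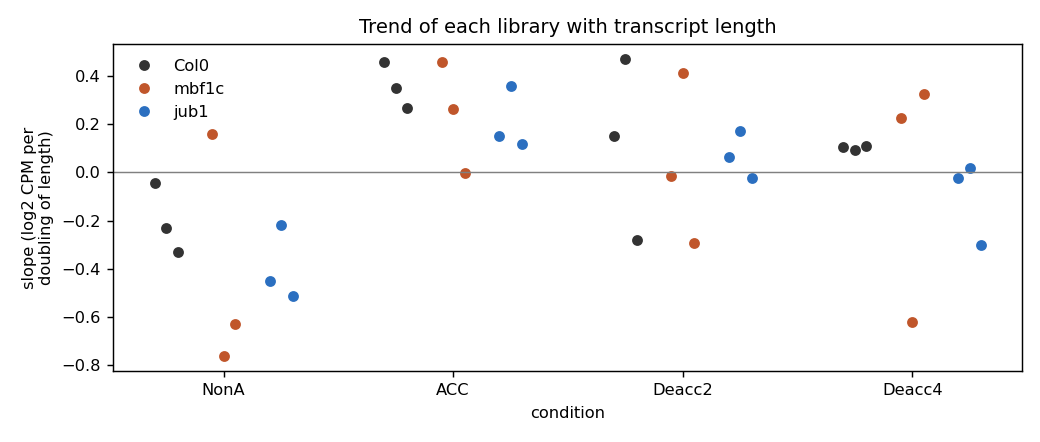
Slope of log2 CPM per doubling of exonic length (y axis) for each of the 36 libraries, by condition (x axis), coloured by line. The mean was −0.334 at NonA and 0.269 at ACC, and libraries of one condition overlapped those of others.

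The gene mutated in each line was examined first. MBF1C was at 3.50 ± 0.42 CPM (SD, n = 3) in Col0 at NonA, 0.717 ± 0.0456 at ACC, 4.16 ± 1.39 at Deacc2 and 3.77 ± 1.17 at Deacc4. In mbf1c it was at 1.06 ± 0.676, 0.365 ± 0.0213, 0.779 ± 0.30 and 0.939 ± 0.118 CPM in the same order, and in jub1 at 3.05 ± 0.537, 0.836 ± 0.193, 3.87 ± 0.360 and 4.21 ± 1.44 CPM. JUB1 was at 4.11 ± 1.41 CPM in Col0 at NonA, 0.893 ± 0.495 at ACC, 8.50 ± 2.27 at Deacc2 and 5.72 ± 2.81 at Deacc4. In jub1 it was at 0.623 ± 0.151, 0.399 ± 0.0343, 1.14 ± 0.211 and 1.08 ± 0.487 CPM, and in mbf1c at 1.75 ± 0.957, 0.964 ± 0.702, 6.32 ± 4.76 and 5.13 ± 3.79 CPM.

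Averaged over the conditions, MBF1C was lower in mbf1c than in Col0 by a log2 difference of −1.73 ± 0.18 (SE, edgeR adjusted p = 1.2e-06), and JUB1 was lower in jub1 by −2.29 ± 0.334 (adjusted p = 0.000779). Within conditions, MBF1C in mbf1c fell below Col0 at Deacc2 (−2.36 ± 0.356, adjusted p = 0.00211) and Deacc4 (−2.0 ± 0.357, adjusted p = 0.0252), and its log2 differences of −1.61 at NonA and −0.96 at ACC were not called (adjusted p = 0.624 and 1). JUB1 in jub1 had log2 differences of −2.69, −1.20, −2.90 and −2.38 at NonA, ACC, Deacc2 and Deacc4, none called at a single condition (adjusted p of 0.909 or more). At Deacc2 it was called by DESeq2 (−2.89, DESeq2 adjusted p = 0.0452) and with only the compared groups (−2.85, adjusted p = 0.0301). At each condition the 3 mutant libraries lay below the 3 Col0 libraries for the mutated gene, a separation in either direction that chance gives in 10% of cases. Reads were counted without regard to strand, and 25.9% of the exonic bases of MBF1C and 7.8% of those of JUB1 are shared with genes on the opposite strand. The first strand column held 50.4% to 52.0% of the stranded counts, so read strand does not tell opposite genes apart there either. With the first strand column in place of the unstranded one, MBF1C in mbf1c was no longer called on average (−0.44, adjusted p = 0.662), at Deacc2 (−0.52, adjusted p = 1) or at Deacc4 (−0.64, adjusted p = 0.996), and with only the compared groups it was not called at Deacc2 or Deacc4 (adjusted p = 1 for both). MBF1C lost its call on average without replicate 3 (adjusted p = 0.141), at Deacc2 without replicate 1 or 3 (0.105 and 1), and at Deacc4 without replicate 1, 2 or 3 (0.558, 0.335 and 0.918). JUB1 lost its average call without replicate 2 (adjusted p = 0.124) or replicate 3 (0.923).

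In Col0 both genes fell in the cold and rose after it. MBF1C changed by −2.29 ± 0.360 from NonA to ACC (adjusted p = 2.8e-05), and by 2.54 ± 0.359 and 2.40 ± 0.357 from ACC to Deacc2 and Deacc4 (adjusted p = 3.62e-06 and 6.9e-06). The fall of MBF1C was not called with the first strand column (−0.49, adjusted p = 0.177). JUB1 changed by −2.16 ± 0.650 (adjusted p = 0.0101), then by 3.21 ± 0.663 and 2.64 ± 0.651 (adjusted p = 0.000363 and 0.00177). Without replicate 2 the fall of JUB1 was not called (adjusted p = 0.11). Against NonA, MBF1C at Deacc2 and Deacc4 had log2 differences of 0.25 and 0.11, and JUB1 of 1.05 and 0.48, none called (adjusted p of 0.362 or more). In mbf1c, JUB1 rose by 2.74 to Deacc2 (adjusted p = 0.00161) and by 2.46 to Deacc4 (0.00362, 0.0879 with only the compared groups and 0.122 without replicate 3). In jub1, MBF1C fell by 1.83 in the cold (adjusted p = 0.000241, and −0.39 at 0.268 with the first strand column) and rose by 2.17 and 2.29 after it (2.63e-05 and 1.46e-05).

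**Figure D2:**
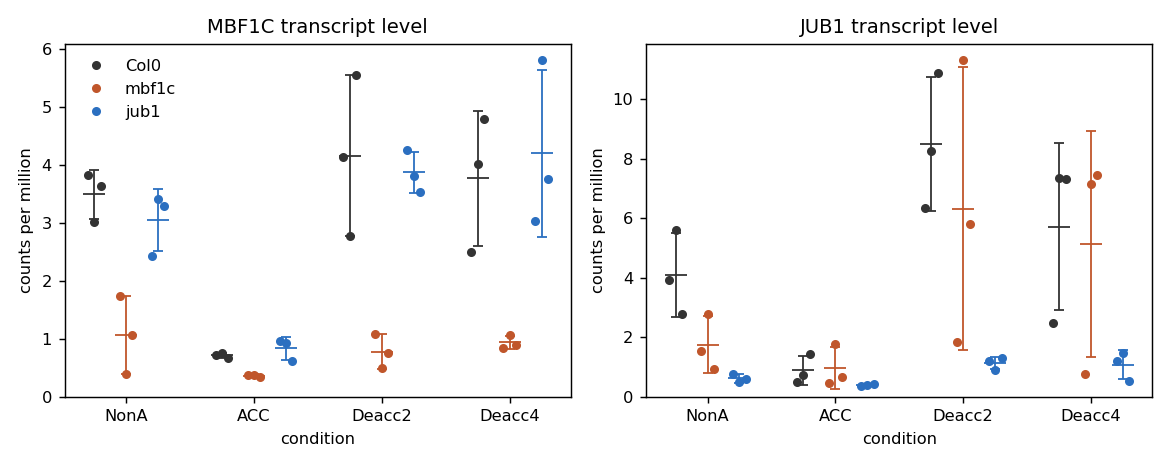
CPM of MBF1C and JUB1 (y axes) in each of the 36 libraries by condition and line, with the mean and SD of 3 libraries. In Col0 both genes were below 1 CPM on average at ACC (0.717 and 0.893).

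Acclimation was read from Col0 at ACC against NonA. Light was 90 µE per square metre and second at ACC and 200 at the other conditions, so temperature and light changed together in every contrast with ACC and their parts cannot be told apart. ELIP1 and ELIP2, early light-induced proteins that bind chlorophyll in thylakoids, had the largest rises, with log2 changes of 8.35 ± 0.902 and 8.16 ± 0.885 (SE, n = 3 per group). ELIP1 reached 2487 ± 1754 CPM (SD) from 7.59 ± 3.16. The cold-regulated genes KIN1 (6.18 ± 0.947) and COR15A (4.99 ± 1.07) and the dehydrin gene LTI30 (5.59 ± 0.620) were also among the 10 largest rises. COR15A, which encodes a chloroplast protein that stabilises membranes in freezing, went from 160 ± 20.9 to 5060 ± 962 CPM. UGT78D3, a flavonol glycosyltransferase gene (5.66 ± 0.709), TT7, the flavonoid 3'-hydroxylase gene (5.30 ± 0.848), and CHS, for the entry enzyme of the flavonoid pathway (5.22 ± 0.725), rose with AT2G23910 (5.24 ± 0.815) and AZI1 (5.01 ± 0.644), a lipid transfer protein gene. The largest falls were of EXPA8 (−6.28 ± 0.743), an expansin gene that loosens cell walls, and HUP54 (−6.08 ± 0.707), a gene of unknown function induced by low oxygen, which went from 53.2 ± 16.0 to 0.750 CPM. GASA6, a gibberellin-responsive gene (−5.91 ± 0.848), SEN1, a gene induced by darkness and senescence (−4.61 ± 0.736), and BXL1, a xylosidase gene (−4.56 ± 0.535), were among the 10 largest falls. The other 5 were AT5G56100, AT1G14250, AT3G55240, AT1G23390 and AT2G15960, at −5.62, −5.58, −4.87, −4.49 and −4.44. The largest adjusted p among these 20 was that of AT1G14250 (0.00117). In all, 4304 genes rose and 4275 fell of 20679 tested, 3013 and 3205 of them by at least 2-fold. Leaving out replicate 1 from every group gave 4257 calls, leaving out replicate 3 gave 4959, and leaving out only Col0 ACC replicate 1 gave 5573.

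Flavonoid genes formed the most uniform rising list in the cold. All 17 rose over all genes and adjusted over the list alone, among them FLS1 (3.84 ± 0.441), MYB111 (2.88) and CHI (2.89), the flavonol synthase, a flavonol regulator and chalcone isomerase (camera adjusted p = 9.41e-11, and adjusted p = 0.142 with an estimated correlation). Within this list 93.8% of the exonic bases of F3H lie opposite another gene and LDOX has a near-identical copy (AT4G22870), so both are uncertain. Of 15 ribosome biogenesis genes 11 rose, 12 adjusted over the list alone, led by FIB2 (2.82 ± 0.283), a fibrillarin gene of rRNA processing, EBP2 (2.42), NOP56 (2.36) and NAP57 (1.82). The list's camera adjusted p was 3.67e-08 (adjusted p = 0.117 with an estimated correlation). Clock genes split 12 up and 2 down of 19, likewise adjusted over the list alone, with the morning genes CCA1 (4.07 ± 0.489) and LHY (4.07 ± 0.622) and LNK1 (1.44) higher and CHE (−2.18) lower. That list had a camera adjusted p of 0.01 (adjusted p = 0.117 with an estimated correlation), and with the length correction 8 rose and 4 fell. In the cold regulon 7 of 20 rose and 1 fell, also adjusted over the list alone: COR15B (4.64 ± 0.676) and COR78 (3.97 ± 0.621) joined LTI30 and KIN1, and RCI2B, named after its value was seen, fell (−1.81). Its camera adjusted p was 0.0141 (adjusted p = 0.522 with an estimated correlation). Abscisic acid genes counted 8 up and 0 down of 18, also adjusted over the list alone, led by CYP707A1 (1.98), which breaks the hormone down, HAB1 (1.67), ABF3 (1.13) and HB12 (1.56). The camera adjusted p of 0.0398 (adjusted p = 0.522 with an estimated correlation) was 0.089 with the length correction, 0.0615 with only the compared groups, and 0.17 and 0.0866 without replicate 1 or 2. ABF3 and HB12 lost their calls without replicate 1 (adjusted p = 0.128 and 0.193) or 2 (0.0564 and 0.0956), and HAB1 without replicate 1 (0.0986).

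Photosynthesis genes fell together: 16 of 19 were called, 17 adjusted over the list alone, and none rose. RBCS2B (−3.44 ± 0.320) and RBCS3B (−3.49), for the Rubisco small subunit, and the antenna genes LHCB6 (−3.45) and LHCA3 (−2.43) led the list (camera adjusted p = 9.41e-11, and adjusted p = 0.266 with an estimated correlation). LHCB1.1, LHCB1.2 and LHCB1.3 are near-identical to one another and LHCA2 has a copy, so their reads could not be assigned with certainty. Gibberellin and brassinosteroid genes counted 0 up and 10 down of 19, 11 down adjusted over the list alone, including the DELLA genes GAI (−1.07) and RGL1 (−1.84) and the brassinosteroid synthesis genes BR6OX1 (−3.57) and CPD (−1.99). Their camera adjusted p was 0.00341 (adjusted p = 0.142 with an estimated correlation). The cell wall list had 7 falls of 13, likewise adjusted over the list alone, with EXPA1 (−3.11), EXPA3 (−1.68) and EXPA11 (−2.30) beside EXPA8 (camera adjusted p = 0.0014, and adjusted p = 0.346 with an estimated correlation). EXPA11 was not called without replicate 2 (adjusted p = 0.0603). Senescence genes gave 5 falls of 12, also adjusted over the list alone: SEN1, the dark-induced genes DIN10 (−4.16) and ASN1 (−2.04), and the chlorophyll breakdown gene PPH (−1.07). Camera gave an adjusted p of 0.0202 (adjusted p = 0.428 with an estimated correlation). Of 17 jasmonate genes 7 fell, also adjusted over the list alone, led by the synthesis genes AOS (−2.38), AOC1 (−2.48) and OPR3 (−1.12) and the repressor gene JAZ2 (−0.72). Without replicate 2 the list's camera adjusted p of 0.0208 (adjusted p = 0.52 with an estimated correlation) became 0.181, and AOC1, OPR3 and JAZ2 lost their calls (0.0505, 0.0953 and 0.0876). JAZ2 was also not called without replicate 1 (0.0828) or with the length correction (0.0998).

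Hypoxia genes, which the series title points to, moved both ways in the cold. Of 21 measured, 3 rose and 9 fell, 3 and 10 adjusted over the list alone. The fermentation genes ADH1 (2.50 ± 0.395) and PDC1 (2.73) and the sucrose synthase gene SUS1 (3.03 ± 0.404) rose (PDC1 was named after its value was seen), while HUP54 and the transcription factor gene LBD41 (−2.13) fell. The list's camera adjusted p was 0.023 (adjusted p = 0.428 with an estimated correlation) and 0.0779 without replicate 2. Sugar and proline genes split 8 up and 3 down of 15, 9 and 3 adjusted over the list alone, with the proline synthesis gene P5CS2 (3.39) and the amylase gene BAM3 (3.83) up and the vacuolar sugar exporter genes ERDL6 (−2.48) and SWEET17 (−3.17) down (camera adjusted p = 0.22). Oxidative and mitochondrial stress genes counted 5 up and 5 down of 18, 6 and 5 adjusted over the list alone, with CAT2 (1.94), GSTU24 (2.91) and NAC013 (1.81) up and CAT3 (−2.06) down (camera adjusted p = 0.819). NAC013 lost its call without replicate 1 (adjusted p = 0.0609). Among 13 heat-shock genes 1 rose and 4 fell, likewise adjusted over the list alone, with HSFB2A (−2.12), HSFB2B (−0.91), ROF2 (−1.43) and DREB2A (1.39) (camera adjusted p = 0.212). DREB2A was not called without replicate 1, 2 or 3 (adjusted p = 0.0707, 0.065 and 0.0739), ROF2 without replicate 1 or 3 (0.103 and 0.105), and HSFB2B without replicate 1 (0.0672). Of 16 cell cycle genes 4 rose and 1 fell, also adjusted over the list alone: the replication genes MCM3 (1.65), MCM5 (1.66) and MCM7 (1.52) rose and CDKB2;1 (−0.94) fell. The list's median was −0.06 and its mean 0.25 (camera adjusted p = 0.778). CDKB2;1 was not called with the length correction (adjusted p = 0.081) or without replicate 1 (0.0984), MCM3 and MCM7 without replicate 1 (0.0519 and 0.0522), and MCM7 and MCM5 without replicate 3 (0.125 and 0.112). None of 17 salicylate defence genes was called (smallest edgeR adjusted p = 0.0803), nor adjusted over the list alone (camera adjusted p = 0.289). The 6 floral and 2 root marker genes measured also had no call (camera adjusted p = 0.964 and 0.819).

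**Figure D3:**
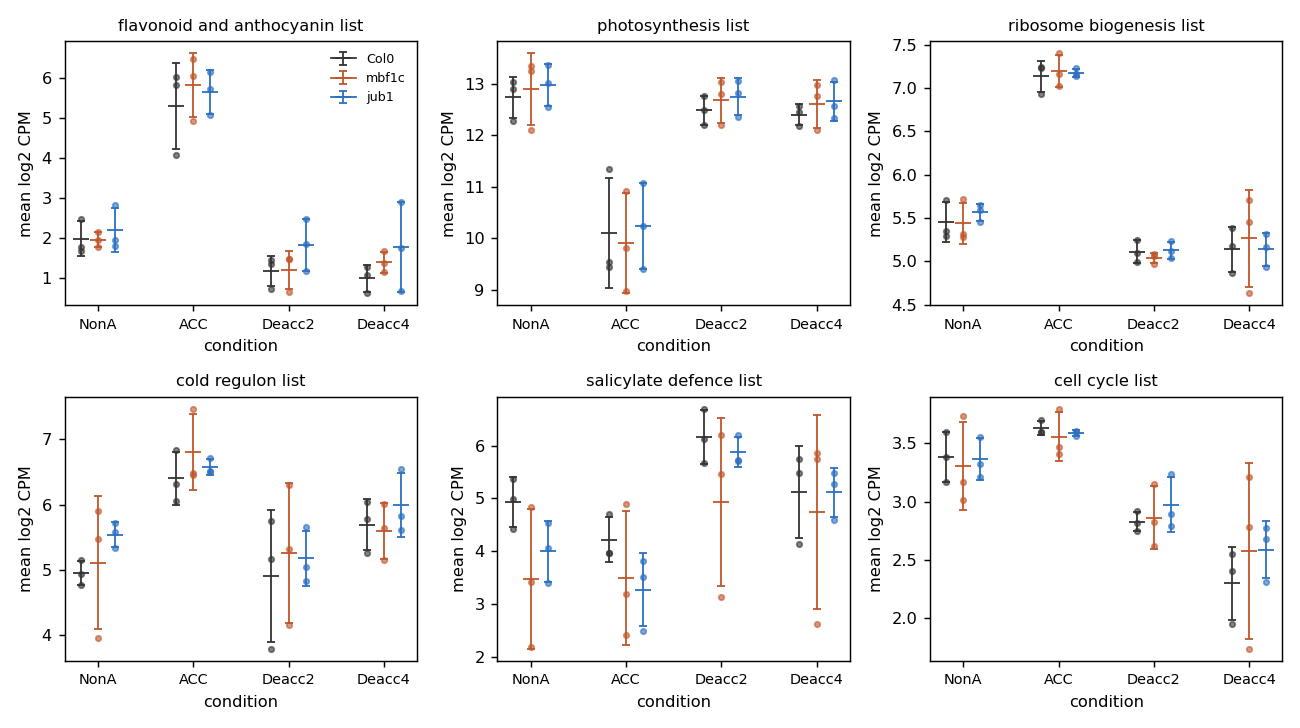
Mean log2 CPM of the members of 6 gene lists (y axes) in each of the 36 libraries by condition and line, with the mean and SD of 3 libraries. All 17 flavonoid genes rose in Col0 from NonA to ACC.

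The release of cold was read from Col0 at Deacc2 against ACC. HUP54 (7.19 ± 0.739, SE, n = 3 per group), SEN1 (6.58 ± 0.790), EXPA8 (6.38 ± 0.746), BXL1 (6.09 ± 0.573) and GASA6 (6.00 ± 0.852) had the largest rises, and HUP54 reached 115 ± 7.46 CPM (SD). DIN10, a dark-induced gene of raffinose metabolism (5.42 ± 0.717), and BGAL4, a galactosidase gene (5.22 ± 0.630), were in the same 10 with AT4G10860, AT1G14250 and AT2G05540 (5.79, 5.56 and 5.20). The largest falls were of ELIP2 (−8.84 ± 0.908) and ELIP1 (−8.48 ± 0.905), which ended at 6.95 ± 1.12 CPM. UGT78D3 (−7.07 ± 0.746), the anthocyanin regulator gene TT8 (−6.16 ± 0.786), TT7 (−5.94), CHS (−5.55 ± 0.736), KIN1 (−5.41 ± 0.910), AT3G14395 (−5.98), AT2G23910 (−5.46) and AT5G17040 (−5.39 ± 0.501) completed the 10. Adjusted p-values ran up to 0.000905, again that of AT1G14250. In all, 4505 genes rose and 4063 fell, 3355 and 2988 of them by at least 2-fold. Without replicate 1 in every group 4958 genes were called, and without replicate 3 there were 5388.

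All 17 flavonoid genes fell by Deacc2, also adjusted over the list alone, with FLS1 at −4.44 ± 0.453, MYB111 at −3.67 and CHI at −3.83 (camera adjusted p = 5.8e-13, and adjusted p = 0.15 with an estimated correlation). Ribosome biogenesis genes counted 13 falls of 15, likewise adjusted over the list alone, led by FIB2 (−3.44 ± 0.291), EBP2 (−2.85), BRX1-1 (−2.36) and NAP57 (−2.26), with a camera adjusted p of 7.2e-10 (adjusted p = 0.0669 with an estimated correlation). BRX1-1 was not called with the first strand column (−0.58, adjusted p = 0.194). Photosynthesis genes gave 15 rises of 19, 16 adjusted over the list alone, with RBCS2B at 2.91 ± 0.312, RBCS3B at 2.88, LHCA3 at 2.46 and LHCA4 at 2.46 (camera adjusted p = 1.06e-08, and adjusted p = 0.342 with an estimated correlation). Senescence genes rose in 8 of 12 cases, also adjusted over the list alone, with ASN1 at 3.43 and PPH at 1.90 beside SEN1 and DIN10 (camera adjusted p = 6.57e-05, and adjusted p = 0.209 with an estimated correlation). The salicylate list counted 9 rises of 17, likewise adjusted over the list alone: ICS1 (2.47 ± 0.616), for salicylate synthesis, its exporter gene EDS5 (2.25), FMO1 (4.24) and the regulator gene CBP60G (2.41). Its camera adjusted p was 0.00479 (adjusted p = 0.516 with an estimated correlation). The gibberellin and brassinosteroid list, which holds DELLA genes beside synthesis genes and so is not a measure of growth, rose too. It had 10 up and 1 down of 19, 11 and 2 adjusted over the list alone (GAI 1.33, GA2OX2 1.90, BR6OX1 3.38, RGL1 1.69). The cell wall list had 7 up of 13, also adjusted over the list alone (EXPA1 2.95, EXPA11 2.32, XTH22 1.76). In that order, camera gave adjusted p-values of 0.0125 and 0.00722 (adjusted p = 0.234 and 0.468 with an estimated correlation). XTH22 was not called without replicate 1 (adjusted p = 0.108).

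Cold regulon genes counted 1 up and 6 down of 20 at Deacc2, also adjusted over the list alone, with LTI30 at −4.96 ± 0.597, COR15B at −4.57 and COR78 at −3.65. Their camera adjusted p of 0.0134 (adjusted p = 0.516 with an estimated correlation) was 0.0662 without replicate 2. Hypoxia genes split 5 up and 3 down of 21, likewise adjusted over the list alone: HUP26 (2.72) rose with HUP54, and ADH1 (−3.05 ± 0.402) and PDC1 (−3.59) fell (camera adjusted p = 0.232). Clock genes counted 3 up and 6 down, likewise adjusted over the list alone, with CCA1 at −3.36, LHY at −3.49, LNK1 at −1.27 and ZTL, a photoreceptor gene, at 0.70 (camera adjusted p = 0.0539, and 0.0103 and 0.0448 without replicate 1 or 2). LNK1 and ZTL lost their calls without replicate 1 (adjusted p = 0.0569 and 0.0928). Jasmonate genes gave 7 rises of 17, also adjusted over the list alone, with JAZ2 (0.88), OPR3 (1.11), AOC1 (1.83) and the storage protein gene VSP2 (3.95). The list's camera adjusted p of 0.0224 (adjusted p = 0.516 with an estimated correlation) was 0.0611 without replicate 2. Without replicate 1, JAZ2, AOC1 and VSP2 lost their calls (adjusted p = 0.0615, 0.178 and 0.336), and without replicate 2 AOC1 and VSP2 did (0.0853 and 0.061). Cell cycle genes fell in 8 of 16 cases, 9 adjusted over the list alone, with MCM3 (−1.65), MCM5 (−1.55), MCM7 (−1.39) and the cyclin gene CYCB1;1 (−1.09) (camera adjusted p = 0.0125, and adjusted p = 0.516 with an estimated correlation). Without replicate 3 none of these 4 was called (adjusted p = 0.0519, 0.155, 0.195 and 0.103), and without replicate 1 MCM5, MCM7 and CYCB1;1 were not (0.0673, 0.0753 and 0.0854).

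The remaining lists had no camera call from ACC to Deacc2. Heat-shock genes counted 4 rises of 13, also adjusted over the list alone: HSFB2A (2.49), HSFB1 (2.28), the chaperone gene HSP90-1 (2.75) and ROF2 (1.63) (camera adjusted p = 0.232). HSFB1 and ROF2 lost their calls without replicate 3 (adjusted p = 0.159 and 0.0736). Sugar and proline genes split 5 up and 4 down, 5 and 5 adjusted over the list alone, with ERDL6 (2.53) and the proline catabolism gene PRODH1 (2.34) up and P5CS2 (−2.37) and BAM3 (−3.02) down (camera adjusted p = 0.71). Abscisic acid genes counted 1 up and 3 down, 0 and 1 adjusted over the list alone, with CYP707A1 at −2.33 (camera adjusted p = 0.278). NCED3 (−1.23), ABI2 (−0.84) and HAI1 (2.01) were called, but NCED3 and ABI2 not with the length correction (adjusted p = 0.206 and 0.128) or without replicate 1 (0.214 and 0.235) or 2 (0.13 and 0.215), ABI2 not with only the compared groups (0.0862), and HAI1 not without replicate 1 or 3 (0.141 and 0.595). Oxidative stress genes split 5 up and 4 down, 6 and 5 adjusted over the list alone, with CAT3 (3.12), AOX1D (4.25) and RBOHD (0.83) up and GSTU25 (−3.60) down. Their median was 0.26 and their mean −0.07 (camera adjusted p = 0.71), and GSTU25 and RBOHD lost their calls without replicate 1 (adjusted p = 0.0576 and 0.0689). WOX5 fell (−1.81 ± 0.684, adjusted p = 0.0348), but not with the first strand column (0.117) or without replicate 1, 2 or 3 (0.064, 0.0653 and 0.23). Camera gave adjusted p-values of 0.416 and 0.71 for the root and floral markers, and no floral marker was called.

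After 4 days of release, Col0 at Deacc4 against ACC was compared in the same way. HUP54 (6.93 ± 0.731, SE, n = 3 per group), SEN1 (6.85 ± 0.798), LRX2, a cell wall extensin gene (6.77 ± 1.06), AT2G05540 (6.09 ± 0.673) and GASA6 (5.95 ± 0.850) had the largest rises. ELIP2 (−10.29 ± 0.966), ELIP1 (−10.06 ± 0.965), AT3G14395 (−6.43), UGT78D3 (−6.23) and TT8 (−6.21) had the largest falls. In all, 4460 genes rose and 4829 fell (3346 and 3601 by at least 2-fold), and 5890 were called without replicate 1. All 17 flavonoid genes and 14 of 15 ribosome biogenesis genes fell, with FLS1 at −4.95 and FIB2 at −3.74, also adjusted over the list alone (camera adjusted p = 1.2e-12 and 8.1e-09, and adjusted p = 0.161 and 0.104 with an estimated correlation). Cell cycle genes fell in 13 of 16 cases, likewise adjusted over the list alone, with CYCB1;2 at −1.85 (near-identical to AT1G34460 and so uncertain), CDKB2;2 at −1.46, CYCB1;1 at −1.92 and CYCB1;4 at −1.57 (camera adjusted p = 6.24e-05, and adjusted p = 0.308 with an estimated correlation). Senescence genes rose in 10 of 12 cases, likewise adjusted over the list alone, with DIN10 at 5.77, ASN1 at 3.69 and PPH at 2.1 (camera adjusted p = 6.24e-05, and adjusted p = 0.218 with an estimated correlation). Jasmonate genes rose in 8 of 17 cases, likewise adjusted over the list alone (camera adjusted p = 0.00578, and adjusted p = 0.374 with an estimated correlation). Only CBP60G (1.67) of 17 salicylate genes rose, none adjusted over the list alone, and its call ended without replicate 2 or 3 (adjusted p = 0.17 and 0.0692). With the length correction 6 salicylate genes rose (camera adjusted p in the uncorrected fit 0.18, and 0.0085 without replicate 1). Hypoxia genes split 5 up and 4 down, likewise adjusted over the list alone, with HUP26 at 2.79, ADH1 at −3.65 and PDC1 at −4.73 (camera adjusted p = 0.594).

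Photosynthesis genes rose in 15 of 19 cases at Deacc4 against ACC, 16 adjusted over the list alone (camera adjusted p = 3.6e-08, and adjusted p = 0.308 with an estimated correlation), and cell wall genes split 8 up and 1 down, likewise adjusted over the list alone (0.00121, and adjusted p = 0.308 with an estimated correlation). The cold regulon counted 2 up and 6 down of 20, also adjusted over the list alone, with KIN1 at −5.04, COR15A at −4.44, COR15B at −3.87 and LTI30 at −3.81. Its median was 0.16, its mean −0.71 and the direction of the camera test downward (adjusted p = 0.424). Gibberellin and brassinosteroid genes split 8 up and 2 down, 9 and 3 adjusted over the list alone. Their camera adjusted p of 0.0394 (adjusted p = 0.308 with an estimated correlation) was 0.0562 with the length correction, 0.0723 with the first strand column, 0.0576 with only the compared groups and 0.0838 without replicate 3. Clock genes counted 3 up and 7 down, heat-shock genes 4 and 1, and abscisic acid genes 1 and 5, all unchanged when adjusted over the list alone (camera adjusted p = 0.18, 0.188 and 0.185, the last 0.0127 without replicate 3). Sugar and proline genes counted 5 up and 6 down, 5 and 7 adjusted over the list alone, and oxidative stress genes 5 and 5 both ways (camera adjusted p = 0.872 for each). The oxidative list had a median of −0.30 and a mean of −0.29 while the camera test pointed upward. Of the root markers WOX5 fell (−1.83), but not with the first strand column (adjusted p = 0.0969) or without replicate 1, 2 or 3 (adjusted p = 0.189, 0.0931 and 0.0529), and no floral marker was called (camera adjusted p = 0.594 and 0.734).

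**Figure D4:**
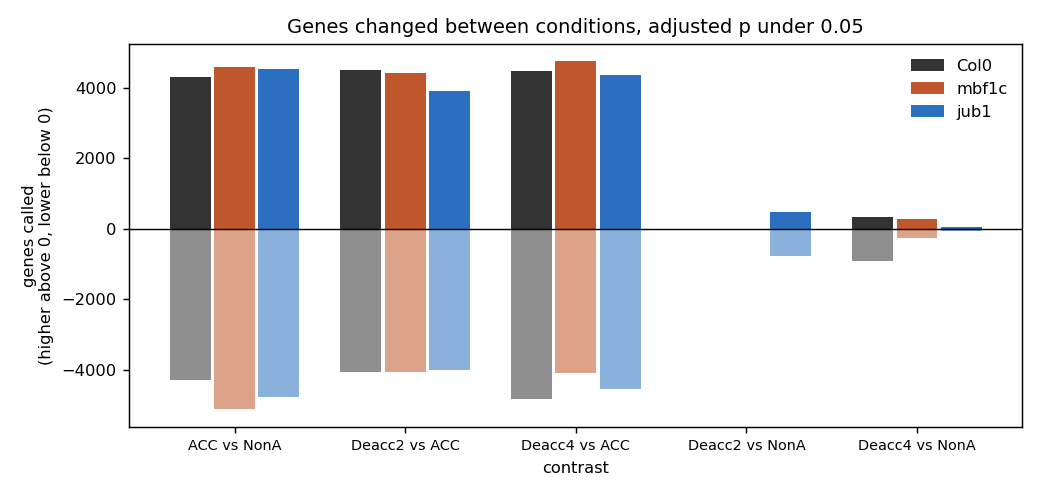
Number of genes that rose (above 0) and fell (below 0) at an adjusted p under 0.05 (y axis) in 5 temperature comparisons (x axis) for each of the 3 lines. Col0 had 4304 rises and 4275 falls from NonA to ACC and 334 and 930 at Deacc4 against NonA.

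What remained after release was read against NonA, where plants were 5 and 7 days younger, so age and release are not separated in these contrasts. At Deacc2, AT5G37540, a gene for an aspartic protease family member, was the single call of 20679 genes in Col0 (log2 change 1.67 ± 0.284, edgeR adjusted p = 0.0493), at 16.9 ± 4.85 CPM against 5.33 ± 1.33 (SD, n = 3). It was not called with RLE scaling (adjusted p = 0.0621), without the filter (0.0538), with the first strand column (0.153), with only the compared groups (0.165), or without replicate 1, 2 or 3 (0.25, 0.273 and 0.427). No gene was called when any Col0 NonA library, or Col0 Deacc2 replicate 2 or 3, was left out. At an unadjusted p under 0.05 there were 3620 genes, where 1034 would be met by chance, and DESeq2 called 231. The replicate block gave 48 rises and 73 falls, though same-number correlations here ran down to −0.039. No member of the 18 lists was called, though 5 cell cycle genes were lower and 4 senescence genes higher adjusted over the list alone (camera adjusted p = 0.00015 and 0.000129, and adjusted p = 0.558 and 0.529 with an estimated correlation). The 17 flavonoid genes all had lower values (median −0.79, camera adjusted p = 0.00215, and adjusted p = 0.558 with an estimated correlation). All 17 salicylate genes had higher ones (median 1.21, camera adjusted p = 3e-04, and adjusted p = 0.558 with an estimated correlation, 0.0956 without replicate 3).

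At Deacc4 against NonA, cell cycle genes formed the largest called group in Col0. Of 16, 10 fell, also adjusted over the list alone, led by the mitotic kinase genes CDKB2;1 (−1.87 ± 0.279, edgeR adjusted p = 0.00105, n = 3 per group) and CDKB2;2 (−1.61) and the cyclin genes CYCB1;2 (−1.93) and CYCB1;4 (−1.67). The list's camera adjusted p was 2.21e-08 (adjusted p = 0.336 with an estimated correlation). The desaturase gene SAD6 had the largest fall (−3.86 ± 0.670), from 31.1 ± 8.51 to 2.15 ± 0.777 CPM, and with the hypoxia genes SUS4 (−3.63), PCO2 (−2.07) and PDC1 (−2.0, named after its value was seen) it fell while PDC2 rose (0.94). This made 1 up and 4 down of 21 hypoxia genes, 3 and 9 adjusted over the list alone (camera adjusted p = 0.0307, adjusted p = 0.549 with an estimated correlation, and 0.0897 without replicate 2). The cold regulon had 3 rises, COR47 (1.55 ± 0.386), LTI30 (1.78) and COR78 (1.85), also adjusted over the list alone (camera adjusted p = 0.00809, adjusted p = 0.689 with an estimated correlation, and 0.0944 without replicate 1). The largest rises were of the wall genes LRX2 (3.54 ± 0.880), XTH18 (2.86 ± 0.719) and EXLA1 (2.75 ± 0.606), the lignin synthesis gene CCOAMT (2.83 ± 0.814) and AT4G16563 (2.39 ± 0.631). The wall gene XTH31 (−3.39 ± 0.774), AT5G38940 (−3.36), AT3G05727 (−2.62) and AT4G22517 (−2.59 ± 0.789) followed SAD6 among the falls. The cell wall list counted 1 up and 1 down of 13, 3 and 1 adjusted over the list alone, with a median of −0.06 and a mean of 0.23 (camera adjusted p = 0.713). AT4G22517 shares 45.2% of its exonic bases with an opposite gene and was not called without the filter (adjusted p = 0.0631) or with the first strand column (0.0921).

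In total 334 genes rose and 930 fell at Deacc4 against NonA, 26.4% upward. The length correction gave 881 and 1182 (42.7% upward), with 9 cell cycle genes falling. DESeq2 called 2282 genes. The count rested on single libraries: it was 274 and 197 without Col0 NonA replicate 1 or 3, and 74 and 455 without Col0 Deacc4 replicate 2 or 3. With a whole replicate number left out it was 17, 584 and 0 for replicates 1, 2 and 3. Of the genes the naming rule gave here, only SAD6 and CDKB2;1 kept their calls without replicate 1, and none did without replicate 3 (adjusted p of 0.193 or more). Without replicate 2, LRX2, CCOAMT, EXLA1, AT3G05727, AT4G22517, COR78, PCO2, HSP18.2, FIB2, CAT3 and SEN1 lost theirs (adjusted p from 0.0505 to 0.0978). The other members called were PPH (1.02) and SEN1 (2.24) of the senescence list, 5 up adjusted over the list alone (camera adjusted p = 0.000305, and adjusted p = 0.385 with an estimated correlation), CAT3 (1.48), XTH22 (1.87), EXPA4 (−1.22), GA3OX1 (−1.26), HSP18.2 (−1.28) and FIB2 (−0.92). The length correction ended the calls of COR78 (adjusted p = 0.0518), FIB2 (0.103) and CAT3 (0.088), that of FIB2 also ended without the filter (0.0837), and that of GA3OX1 without the filter (0.0509) and with the first strand column (0.0504). Flavonoid genes had no call but all 17 had lower values (median −1.10, camera adjusted p = 0.00237, and adjusted p = 0.689 with an estimated correlation), and sugar and proline genes had a camera adjusted p of 0.0483 (adjusted p = 0.549 with an estimated correlation, 0.325 with the length correction).

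The direction of the cold response turned on release. Of the genes that rose from NonA to ACC in Col0, 2965 fell from ACC to Deacc2, against 846 for independent lists of these sizes, and of those that fell 3085 rose, against 931. No gene moved in the same direction in both steps. By Deacc4 the numbers were 2980 and 2959, and 7 genes fell in both. Both steps share the ACC libraries, and 20 simulations of unchanged groups gave 0 shared calls and a covariance of −0.104, where −1.43 was observed for Deacc2. Each condition had 3 libraries, too few to split, so part of the excess may come from the shared libraries.

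The mutants were then followed through the same steps. In mbf1c 4576 genes rose and 5119 fell in the cold, and in jub1 4538 and 4776. Flavonoid genes rose in 17 of 17 cases in both lines, also adjusted over the list alone (camera adjusted p = 3.3e-11 and 7.04e-11, and adjusted p = 0.161 and 0.124 with an estimated correlation). Photosynthesis genes fell in 19 of 19 cases in mbf1c and 17 in jub1 (19 and 18 adjusted over the list alone), and ribosome biogenesis genes rose in 11 of 15 in each (11 and 12). Cold regulon genes counted 9 up and 1 down in mbf1c and 6 and 1 in jub1, and hypoxia genes 3 up and 10 down and 3 and 9 (3 and 10 in each adjusted over the list alone). From ACC to Deacc2, 4404 genes rose and 4051 fell in mbf1c, and 3902 and 3995 in jub1. All 17 flavonoid genes fell in both, and 14 of 15 ribosome biogenesis genes, also adjusted over the list alone, with adjusted p = 0.0509 and 0.041 with an estimated correlation, the second being the one list and line where a called list stayed under 0.05. Hypoxia genes split 9 up and 3 down in mbf1c and 4 and 3 in jub1 (10 and 3, and 4 and 3, adjusted over the list alone). At Deacc4 against ACC, mbf1c had 4742 rises and 4087 falls and jub1 4370 and 4531, and hypoxia genes split 10 up and 3 down and 5 and 3, likewise adjusted over the list alone. Without mbf1c ACC replicate 1 the cold count of mbf1c was 6351, without jub1 ACC replicate 2 that of jub1 was 6046, and with only the compared groups mbf1c had 4672 in the cold and 3426 at Deacc4.

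Cold responses overlapped between lines. Col0 and mbf1c shared 3784 rises and 3944 falls, against 952 and 1058 for independent lists, and Col0 and jub1 shared 3753 and 3832, against 945 and 987. No gene was called in opposite directions in either pair. The log2 changes correlated across genes with r = 0.934 and 0.933, and these comparisons share no library. From ACC to Deacc2 Col0 shared 3832 rises and 3504 falls with mbf1c and 3533 and 3375 with jub1.

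Against NonA the mutants differed in count at each stage of release. At Deacc2, 5 genes rose and 7 fell in mbf1c, and 483 and 768 in jub1 (38.6% upward, 56.0% with the length correction at 762 and 599). At Deacc4 the numbers were 284 and 260 in mbf1c and 46 and 77 in jub1 (37.4% upward, 55.2% with the length correction at 527 and 427). The replicate numbers paired the jub1 libraries of Deacc4 and NonA, and with the replicate block 1101 genes were called there. Counts at an unadjusted p under 0.05 were 4601 and 5094 in mbf1c and 6041 and 4375 in jub1, and the difference between lines was not tested for these contrasts. Every one of these counts moved by over 1.5 times when single libraries were left out. For mbf1c at Deacc2 it was 3790, 0 and 0 without NonA replicates 1, 2 and 3 and 1012, 0 and 403 without Deacc2 replicates 1, 2 and 3. For mbf1c at Deacc4 it was 3902, 210 and 0 without those of NonA and 1021, 3162 and 0 without those of Deacc4. In jub1 at Deacc2 it was 0 without NonA replicate 1 or 3 and 2, 0 and 0 without Deacc2 replicates 1, 2 and 3, and at Deacc4 it was 2, 24 and 0 without those of NonA and 4, 0 and 458 without those of Deacc4. At Deacc4, 119 rises and 148 falls were shared by Col0 and mbf1c (4.59 and 11.7 for independent lists) and 31 and 56 by Col0 and jub1 (0.743 and 3.46), and none was opposite.

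Few genes distinguished mbf1c from Col0. AT1G64795 was at 8.80 ± 4.54 CPM in mbf1c (SD, n = 12), 0.0311 ± 0.0393 in Col0 and 0.139 ± 0.0866 in jub1, and was called at NonA, ACC, Deacc2 and Deacc4 (adjusted p = 0.000302, 0.000107, 0.000112 and 6.3e-05). Its exonic bases are shared to 70.6% with AT1G64790 on the opposite strand, so its reads are uncertain. AT5G11330, for a monooxygenase family member, was at 9.21 ± 1.91 CPM in mbf1c against 28.1 ± 6.66 in Col0 and 25.7 ± 5.20 in jub1. It fell at NonA (−1.52 ± 0.216 log2, adjusted p = 0.00109), Deacc2 (−1.94 ± 0.217) and Deacc4 (−1.77 ± 0.217), and on average by −1.58 ± 0.108 (adjusted p = 7.76e-11). With MBF1C and AT2G34190 (1.38 ± 0.237 at Deacc4, adjusted p = 0.0182), these were all the calls at single conditions: 1 up and 1 down at NonA, 1 up at ACC, 1 up and 2 down at Deacc2, and 2 and 2 at Deacc4. Averaged over conditions, AT1G75945 was also higher (1.67 ± 0.265, adjusted p = 0.00394), and AT2G01422 (−2.87 ± 0.481, 0.00747) and AT5G03090 (−3.77 ± 0.651, 0.0132) were lower, which made 2 up and 4 down. AT2G01422 and AT5G03090 were not called with the condition-specific replicate block (adjusted p = 0.0557 and 0.0563). AT2G34190, AT1G75945, AT2G01422 and AT5G03090, and AT1G64795 after NonA, fell outside the rule for named genes and were chosen after their values were seen. Counts at an unadjusted p under 0.05 were 438, 84, 240 and 950 at NonA, ACC, Deacc2 and Deacc4, and 1647 on average. Chance would give 1034, so the counts at single conditions lay below it. The replicate numbers paired these libraries, and with the block 2 genes were called at ACC in place of 1.

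Leaving out replicate 3 ended all calls of mbf1c at single conditions (adjusted p from 0.116 to 1), including those of AT1G64795 (0.891, 0.589, 0.212 and 0.116 in order of condition) and AT5G11330 (1, 0.212 and 0.681 where called). The log2 differences kept their direction without it, at 8.18, 7.405, 8.77 and 11.4 for AT1G64795 and −1.50, −1.94 and −1.75 for AT5G11330. At NonA both also lost their calls without replicate 1 (0.0555 and 0.0634), and AT5G11330 without replicate 2 (0.128). AT2G34190 was not called without replicate 1 or 2 (0.921 and 0.637) or without the filter (0.0966). On average AT1G75945 and AT5G03090 lost their calls without replicate 1, 2 or 3 (0.569, 0.0988 and 0.318 for the first, 0.697, 0.329 and 0.932 for the other), and AT2G01422 without replicate 1 or 3 (0.697 and 0.932). With only the compared groups AT1G64795, AT5G11330 and AT2G34190 were not called at NonA, Deacc2 or Deacc4 (adjusted p of 0.671 or more), and AT1G75945 was not called on average (0.0688). DESeq2 called 13 genes on average. At Deacc4 the edgeR count was 2 without Col0 replicate 2 or 3 or without mbf1c replicate 1 or 2.

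In jub1 no gene was called against Col0 at a single condition by edgeR, with 335, 129, 288 and 819 genes at an unadjusted p under 0.05 and 0, 3, 2 and 6 calls by DESeq2 at NonA, ACC, Deacc2 and Deacc4. The unadjusted counts were all below the 1034 that chance would give. Averaged over conditions, AT3G22235 was lowest relative to Col0 (−7.16 ± 0.792, adjusted p = 1.44e-05), at 1.54 ± 4.73 CPM (SD, n = 12) against 52.4 ± 31.8. That mean rests on jub1 NonA replicate 1, at 16.6 CPM, and was 0.171 CPM over the other 11 jub1 libraries. It has a near-identical copy, AT3G22231, and is marked as uncertain. JUB1 was called on average (−2.29 ± 0.334), and with AT2G05914 (−2.56 ± 0.337, adjusted p = 0.000252) and AT2G06995 (−1.86 ± 0.274, 0.000779) it made 4 falls. AT1G06673 (3.82 ± 0.712, 0.0356), AT1G75945 (1.44 ± 0.264, 0.0261) and AT3G05955 (1.84 ± 0.264, 0.000779) were the 3 rises. AT1G06673 was not called with the condition-specific replicate block (adjusted p = 0.0615). These genes other than JUB1 and AT3G22235 were chosen after their values were seen. Without replicate 1 AT1G06673, AT1G75945, AT2G05914, AT2G06995 and AT3G05955 lost their calls (adjusted p = 0.407, 0.861, 0.418, 0.0764 and 0.418), without replicate 2 AT1G06673 and AT1G75945 did (0.237 and 0.0535), and without replicate 3 AT1G75945, AT2G06995 and AT3G05955 did (0.923, 0.748 and 0.535). Since 0 rises and 2 falls were called without replicate 3, AT1G06673 had no call there either. At an unadjusted p under 0.05 there were 1941 genes on average over conditions, where 1034 would be met by chance, and DESeq2 called 27. AT1G75945, the one call shared by both mutants, was at 25.2 ± 19.3 CPM in mbf1c, 21.5 ± 12 in jub1 and 7.48 ± 3.09 in Col0.

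Salicylate defence genes had lower values in both mutants at some conditions, with no member called. In mbf1c the median log2 difference from Col0 was −0.82 at NonA, −0.30 at ACC, −0.72 at Deacc2 and −0.44 on average (camera adjusted p = 1.8e-09, 2.18e-06, 1.19e-11 and 5.11e-10, and adjusted p = 0.94, 0.607, 0.865 and 0.614 with an estimated correlation), and −0.02 at Deacc4 (camera adjusted p = 0.272). In jub1 it was −0.72 at NonA, −0.85 at ACC and −0.60 on average (1.14e-05, 1.33e-08 and 0.000749, and adjusted p = 0.781, 0.691 and 0.635 with an estimated correlation), and −0.41 at Deacc2 and −0.18 at Deacc4 (camera adjusted p = 0.226 and 0.972). At Deacc2 the list was called without replicate 1 (2.23e-05) and with only the compared groups (0.00297), and at Deacc4 without replicate 1 (0.00191). Without replicate 3 the list was not called in mbf1c at ACC (0.135) or in jub1 at ACC (0.0508) or on average (0.257). Flavonoid genes had higher values in jub1 at Deacc2 (median 0.75), Deacc4 (0.93) and on average (0.57), with 0, 0 and 6 rises adjusted over the list alone (camera adjusted p = 2.6e-06, 1.2e-05 and 4.68e-06, and adjusted p = 0.674, 0.675 and 0.561 with an estimated correlation). In mbf1c at ACC, flavonoid (0.46), cold regulon (0.52) and abscisic acid genes (0.38) had higher medians and hypoxia genes a lower one (−0.31), none called adjusted over the list alone (3.16e-07, 0.000103, 3.16e-07 and 0.000139, and adjusted p = 0.442, 0.607, 0.319 and 0.319 with an estimated correlation). Cell cycle genes at Deacc4 had 2 rises adjusted over the list alone in each mutant, with medians of 0.47 and 0.45 (0.0304 and 0.00417, and adjusted p = 0.863 and 0.675 with an estimated correlation). In mbf1c this was not called with the length correction (0.0512) or without replicate 1 or 3 (0.439 and 0.162). In jub1 at Deacc2, where the numbers paired the libraries, the cold regulon had a camera adjusted p of 0.0535, and 0.0381 with the replicate block. Log2 differences between mutant and Col0 followed transcript length across genes, with a rho of −0.410 for mbf1c and −0.492 for jub1 on average. Both mutants share the Col0 libraries, and the covariance of their log2 differences was 0.154, 0.081, 0.063 and 0.138 at NonA, ACC, Deacc2 and Deacc4, against 0.150, 0.120, 0.113 and 0.113 in simulations of unchanged groups. Averaged over conditions it was 0.058 against 0.031 (SD 0.001), above what the shared libraries gave in simulation. The simulated libraries of a condition did not differ in length trend, so this excess cannot be assigned to the mutations.

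Whether a mutant responded differently to temperature was tested by interaction. No gene was called by edgeR or by DESeq2 in any of the 6 tests, and 62, 84 and 229 genes in mbf1c and 76, 98 and 150 in jub1 had an unadjusted p under 0.05 for ACC against NonA, Deacc2 against ACC and Deacc4 against ACC. All 6 counts were below the 1034 that chance would give, so the lack of calls does not show that the lines responded alike. Hypoxia genes had a higher change in mbf1c than in Col0 from ACC to Deacc4, with a median difference of 0.55 and 1 member called adjusted over the list alone (camera adjusted p = 0.000675, and adjusted p = 0.569 with an estimated correlation). In simulated data with 200 genes changed, the interaction test recovered 33% of genes changed by a log2 of 2 and 1% of those changed by a log2 of 1.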

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

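The length correction, with and without the replicate block, and the condition-specific replicate block were chosen after the data were seen; the other alternatives were fixed before. Counts of genes changed within 1.5 times of the reported ones are not repeated here. The large temperature contrasts (ACC against NonA, and Deacc2 and Deacc4 against ACC) stayed within 1.5 times in all 3 lines under every alternative other than leaving out libraries, except that with only the compared groups mbf1c had 4672 genes at ACC against NonA and 3426 at Deacc4 against ACC. Leaving out the organellar genes moved no count by that much. Where only the compared groups were fitted, the spread came from fewer samples and from those groups alone. Counts then moved both ways: at Deacc4 against NonA from 1264 to 5399 in Col0 and from 544 to 0 in mbf1c. The cause of these and the other moves was not tested.

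The contrasts with NonA after release moved most. For Deacc2 and Deacc4 against NonA, DESeq2 called 231 and 2282 genes in Col0, 1221 and 1900 in mbf1c, and 2909 and 1170 in jub1. Without the filter the counts were 0 and 837 in Col0, 0 and 133 in mbf1c, and 602 and 0 in jub1. With only the compared groups they were 0 and 5399, 0 and 0, and 5734 and 696. RLE scaling gave 0 genes at Deacc2 in Col0 and 2 in mbf1c, and the first strand column gave 0 and 1. The length correction gave 2063 at Deacc4 in Col0 and 954 at Deacc4 in jub1. At Deacc4 in Col0 the share of rises was 26.4% and became 41.1% without the filter, 40.8% with the first strand column, 42.7% with the length correction and 52.0% with only the compared groups. Apart from Deacc2 against NonA in Col0 and mbf1c, where it gave 0 and 2 genes, RLE scaling moved no share of a temperature contrast by more than 5.08 points.

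Mutants against Col0 gave small counts throughout. At ACC for mbf1c, DESeq2 called 2 genes and the first strand column 4. With only the compared groups mbf1c had 0 genes at NonA, 0 at Deacc2 and 0 at Deacc4, and jub1 2 at Deacc2 and 1 at Deacc4. For jub1 at ACC, Deacc2 and Deacc4, DESeq2 called 3, 2 and 6 genes and the length correction 1, 2 and 4, and the first strand column called 1 at ACC and 1 at Deacc2. Averaged over conditions, DESeq2 called 13 in mbf1c and 27 in jub1, the length correction 11 and 12, and the first strand column 11 in jub1. MBF1C in mbf1c at ACC against NonA reversed with the first strand column (0.162, adjusted p = 0.667). That column splits reads over opposite genes by read strand, and 25.9% of the exonic bases of MBF1C lie opposite other genes. The strand columns held near-equal shares of the counts, so read strand does not tell which of the opposite genes a read came from.

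With the replicate block, Deacc2 and Deacc4 against NonA gave 121 and 2346 genes in Col0, 823 and 1742 in mbf1c, and 2717 and 1101 in jub1. It gave 2 for mbf1c against Col0 at ACC, 1 for jub1 against Col0 at Deacc4 and 15 for jub1 averaged. With the length correction and the replicate block the counts against NonA were 272 and 3172, 660 and 1961, and 2589 and 2024. The same fit gave 2 for mbf1c at ACC, 1, 2 and 6 for jub1 at ACC, Deacc2 and Deacc4, and 13 and 23 averaged for mbf1c and jub1. The condition-specific replicate block gave 16 for jub1 averaged. The numbers pair the libraries in 8 of 23 contrasts only, and among those the replicate block moved only the counts of jub1 at Deacc4 against NonA and of mbf1c against Col0 at ACC by over 1.5 times. Among these contrasts it also added the cold regulon in jub1 against Col0 at Deacc2 (camera adjusted p = 0.0381) and changed no other call. In the other contrasts libraries also share the number in their titles, but at least 1 same-number correlation was 0.1 or less. Over all groups, same-number correlations ran down to −0.611.

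Leaving out each replicate number or library in turn gave these ranges of counts. For Col0 they were 4257 to 8243 at ACC against NonA, 4958 to 8231 and 5890 to 8885 at Deacc2 and Deacc4 against ACC, and 0 to 1 and 0 to 1008 at Deacc2 and Deacc4 against NonA. In mbf1c they were 6000 to 11666, 4636 to 8075, 5674 to 9096, 0 to 3790 and 0 to 3902 in the same order, and in jub1 4603 to 9289, 4515 to 7135, 5894 to 8330, 0 to 906 and 0 to 458. Against Col0, mbf1c ranged over 0 to 2 at NonA, 0 to 1 at ACC, 0 to 3 at Deacc2, 0 to 3 at Deacc4 and 2 to 9 averaged, and jub1 over 0 to 1 at each condition and 2 to 10 averaged. The interactions stayed at 0 under these settings, and with DESeq2. Where a group was left with 2 libraries the shared spread of all groups was used. The largest count, 11666, came without mbf1c NonA replicate 1 in the cold contrast of mbf1c.

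Of the fold changes of named genes, DESeq2 kept 456 and added a call to 21. The replicate block kept 462 and added 15, RLE scaling kept 475, added 1 and ended 1, and leaving out the organellar genes kept 477. The first strand column kept 445, added 3, ended 15 and reversed 1. The length correction kept 462, added 7 and ended 8. The condition-specific replicate block kept 48 and ended 3, and for the list tests it kept 170 and added 10. Without the filter 470 were kept and 6 ended. With only the compared groups 416 were kept, 44 added and 17 ended. Leaving out replicates kept 1234, added 4 and ended 175. Of the list tests, 196 kept their side of the threshold with an estimated correlation and 74 lost it. The length correction kept 262 and ended 8, and leaving out replicates kept 721, added 48, ended 40 and reversed 1: the jasmonate list in jub1 against Col0 averaged, which ranged from an adjusted p of 2.04e-13 without replicate 3 to one of 0.535, with the direction reversed, without replicate 1. At these depths and with 3 libraries per group, the edgeR test recovered 72% of simulated log2 changes of 2 and 8% of those of 1 for Col0 at ACC against NonA when 200 of 20679 genes were changed, and these shares do not carry over to contrasts with more changed genes.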

Other observations

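The tests of transcript length on the axis within groups, of position beside the mutated gene, of RNA mixed into a library, of the spread of the salicylate list and of other splits of the libraries were chosen after the result was seen.

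Libraries of a group parted along a shared axis that held 40.1% of the variance within groups. The axis followed exonic length across genes, which are not independent replicates (rho = −0.645 over 20547 genes), and taking out a trend with length lowered the common dispersion by 28.7%, so transcript length bias is a candidate explanation. Library depth is argued against: over the 36 libraries r was −0.132 (permutation p = 0.444), rho −0.0399 (permutation p = 0.817), and r 0.0171 without the 2 libraries farthest from the median depth. GC content stays open, with a rho across genes of −0.21, and −0.0937 with length held. RNA integrity per library, or a difference between plants, could give the same values and was not tested.

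AT1G64795, AT5G11330 and AT3G22235 each marked a line when averaged over conditions. A position beside the mutated gene is argued against for these 3, as 0 of the 3 lie on the chromosome of the gene mutated in their line. Among the other genes called on average in jub1, AT2G05914 and AT2G06995 lie on the chromosome of JUB1 by their locus codes. AT1G06673, AT1G75945 and AT3G05955 do not. Position was not tested for these other genes. For reads moved between near-identical copies, 0 copies moved the other way with an unadjusted p under 0.05. AT3G22231, 97.8% identical to AT3G22235 over 367 bases, differed by 0.36 ± 0.414, a spread too wide to decide, so this explanation stays open. A changed segment over several genes stays open: the largest difference of 12 neighbours was 0.409 ± 0.189 (SE, AT3G22230), within 1 SE of the bound of 0.5 set beforehand, and none was called. A difference between the lines outside the mutated genes may explain AT1G64795, AT5G11330 and AT3G22235 and was not tested. AT3G22235 was also at 16.6 CPM in jub1 NonA replicate 1 and at most 0.613 in the 11 other jub1 libraries. RNA of Col0 mixed into that library stays a possible explanation, since a share of 27.8% would put JUB1 at 1.54 CPM and it was at 0.782, above the other jub1 NonA libraries (0.482 and 0.605), while RNA of mbf1c is argued against, since AT1G64795 was at 0.253 CPM where 2.29 would be needed.

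Salicylate defence genes differed from Col0 by a mean log2 of −0.943 in mbf1c and −0.54 in jub1. Transcript length is argued against as the whole cause, since the length correction left ratios of 1.02 and 1.03 of these differences. Spread between libraries stays a candidate explanation: line labels permuted within conditions gave two-sided permutation p-values of 0.0468 and 0.0308, which became 0.281 and 0.277 adjusted over 36 tests. The salicylate list did not have the smallest permutation p-values. Root markers in mbf1c had 0.0111, and clock and senescence genes in jub1 had 0.0233 and 0.0258, each 0.277 adjusted over the 36 tests. As the numbers pair mbf1c with Col0, all 4096 sign flips of the 12 differences within pairs (8 of them negative) were also tried. The exact two-sided p was 0.0161, which became 0.145 adjusted over 18 tests. The permutations and the flips both take the conditions as independent. The differences instead followed the replicate number: −2.80 to −1.50 for replicate 1, −0.528 to 0.917 for replicate 2 and −1.53 to 0.263 for replicate 3. The p-values are therefore too small, and flips of 3 whole numbers cannot give one under 0.05. Without replicate 1 the difference was −0.369 in mbf1c and −0.933 in jub1, and an effect of the mutations was not tested apart from this spread.

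Other splits of the same libraries were refitted with only the compared groups. Contrasts of 3 against 3 have 10 splits, too few for a share under 0.05. In Col0 the real counts were 11348 at ACC against NonA, 8150 and 11383 at Deacc2 and Deacc4 against ACC, and 5399 at Deacc4 against NonA. In mbf1c they were 4672 at ACC against NonA and 6058 and 3426 at Deacc2 and Deacc4 against ACC. In jub1 they were 10149, 9977 and 9226 in that order, and 5734 and 696 at Deacc2 and Deacc4 against NonA. In each of these the real split was the 1 split of 10 with as many genes and the highest other gave 0. Col0 at Deacc2 against NonA gave 0 in all 10 splits. In mbf1c the real counts against NonA were 0 at both stages, with 2149 and 7232 as the highest others.

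For mbf1c against Col0 the real counts were 0 at NonA (highest other 0), 1 at ACC (0), 0 at Deacc2 (3082) and 0 at Deacc4 (0). For jub1 they were 0 at NonA (highest other 425), 0 at ACC (3488), 2 at Deacc2 (0) and 1 at Deacc4, where 2 of 10 splits gave as many and the highest other 554. The splits that called 425 to 3488 genes, where the real ones called 0 or 1, parted the libraries along something other than line. Those of 425, 3082 and 3488 put the 3 lowest slopes with transcript length together. Their slopes reached −0.328, −0.016 and 0.269, and those of the other libraries began at −0.232, 0.152 and 0.348. The split of 554 did not: it joined slopes of −0.024, −0.303 and 0.106, away from 0.019. Length as the cause of these calls was not tested. Where the numbers pair the libraries, the 4 splits that part every pair gave 0 as the highest other, and the 3082 came from a split that kept a pair together. Averaged over conditions, 40 splits of line labels within conditions were made. For mbf1c the real count was 6, reached by 1 of 40 with 0 as the highest other. It was also reached by 1 of 100 drawn splits that part every pair, with 2 as the highest other. In both sets that 1 split was the real one. A chance split drawn apart in each condition is thus argued against for this count, but only if conditions are independent. Same-number correlations in mbf1c were 0.706, 0.174 and 0.541 at ACC against NonA, and 0.602, 0.043 and −0.512 at Deacc4 against ACC. Libraries of one number may therefore vary together over conditions. Splits that swap whole replicate numbers are too few for a share under 0.05, so chance at that level is not excluded. In the fit of all groups the count was 2 without replicate 3. For jub1 the real count was 10, reached by 2 of 40 with 1403 as the highest other, so chance cannot be excluded. For the 6 interactions the real count was 0, which any split matches, so the shares given next were fixed in advance and do not bear on chance. All 40 splits gave as many, with highest others of 5642, 0 and 813 for mbf1c and 0, 2 and 4096 for jub1 in the order of the temperature steps. Of the 32 splits that part every pair, all 32 gave as many in each mbf1c interaction, with 2 as the highest other, so the 5642 and 813 came from splits that kept pairs together.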
